A study of Phaseolus vulgaris and Phaseolus lunatus with 12 samples.

How the data were processed

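RNA sequencing measured the leaf transcripts of 2 bean species, *Phaseolus vulgaris* (common bean, cultivar California Red Kidney) and *Phaseolus lunatus* (lima bean, variety Peladilla), with and without the spider mite *Tetranychus urticae*. Per the labels, plants were 3 weeks old, grown at 23 °C with 16 h of light and 8 h of darkness, and the first true leaf was sampled. Detached leaves carried 50 adult females per leaflet or none, and were frozen at 24 h post infestation. Total RNA was extracted with TRIzol and cleaned on RNeasy columns, and libraries were made with the NEBNext Ultra kit, per the labels' protocols. Each of the 4 groups holds 3 libraries, and the labels do not say whether each library came from a separate plant, so every p-value measures the spread between libraries as labelled. The labels give no batch, date or time of day.

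The deposited values are raw read counts per gene, in 1 table per species with 1 column per library. The submitters' processing notes name HISAT2, featureCounts and DESeq2, with no version, role or setting for any of them. The values are whole numbers and the column totals differ, so no scaling had been applied to them. The genome builds and annotation releases are not given in the sources used here, so coordinates are printed as the deposited tables give them, without a build. Whether counting used strand is not stated either, so reads of overlapping or antisense genes cannot be separated. Members of families with near-identical copies, such as Kunitz inhibitors, light-harvesting proteins, histones and ribosomal proteins, are uncertain as single genes for the same lack of detail on how shared reads were counted. Gene lengths in bases, deposited in the same tables, served only to match random lists.

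The *P. vulgaris* table held 29324 genes, of which 1379 carried a product name and 10537 a domain family. The *P. lunatus* table held 43997 genes, of which 20825 carried a product name, worded like best matches in a protein database, and 12526 a domain family. No gene ID of either table matched the reference table of *P. vulgaris* (assembly P. vulgaris v2.0, 0 IDs matched), so names come from the deposited tables alone. The tables share no gene IDs and no map of orthologs was at hand, so single genes were not compared between the species.

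Total counts ran from 17264823 to 19343807 per library in *P. vulgaris* and from 13317991 to 17255676 in *P. lunatus*. A floor of 3 counts summed over the 3 libraries of a group stands in for a group with 0 counts, and it covers counting error only. No within-group pair of libraries looked like a copy of another, by the excess of their differences over counting error.

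Each species was fitted alone with edgeR (version 4.0.16, in R 4.3.3), with TMM scaling, the filterByExpr filter on low counts, the quasi-likelihood test of infested against control, and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p below 0.05. CPM values are counts scaled to the TMM-adjusted library size, and log2 CPM uses a prior count of 2. The 39 gene lists were fixed by words in product names before the data were examined, and were tested with camera (limma 3.58.1, preset correlation of 0.01) where at least 5 members were measured, with Benjamini-Hochberg adjustment over the lists. Each list was tested again with camera's estimated correlation and with fry, which asks whether a list's own genes move one way and compares it with no other genes. Neither variant was run on the simulated counts described below, so how often each finds a real shift is not known. Because few *P. vulgaris* genes carry a product name, 294 sets made from the domain family column (at least 5 tested members in both species) were added after the annotation had been seen. The species difference was the interaction of species and infestation in limma, on the mean log2 CPM of each list or family per library, over all 12 libraries. Here a positive value means that the signed effect is higher in *P. lunatus*, so a deeper fall in *P. lunatus* gives a negative value.

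Genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 1 and ranges that do not overlap, and the 3 called members of each list with the smallest p. It names genes with a product name only. Domain families identify further *P. vulgaris* genes, chosen by the same rule after the annotation had been seen. Any gene outside the rule is said to be chosen after its values were seen.

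The fits were tested on simulated counts, with 10 simulations per species in which 200 genes above a minimum mean CPM were changed. In *P. vulgaris* (19360 genes), 71.4% of 2-fold and 96.1% of 4-fold changes were recovered. In *P. lunatus* (18523 genes), 63.6% of 2-fold and 96.2% of 4-fold changes were recovered. False calls made up 8.92% of the calls on average in *P. vulgaris* (5.88% to 11.9%) and 8% in *P. lunatus* (5.1% to 10.6%), which lies above the nominal 5% share. The called genes may thus hold somewhat more false calls than the threshold names. The 200 changed genes lie near the 189 called in *P. vulgaris* but far below the 3170 called in *P. lunatus*. The share of false calls among those 3170 is therefore not given by these simulations. Of 390 random lists per species, 1 passed camera in *P. vulgaris* and 0 in *P. lunatus*, and the planted list passed in 10 of 10 simulations of each species. The simulated genes varied independently of each other, so these counts do not show how often camera falsely passes a list of correlated genes.

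Alternatives tried were median-ratio, upper-quartile and unscaled size factors, DESeq2 (version 1.42.0), no low-count filter, a filter of at least 1 CPM in 3 libraries, a robust quasi-likelihood fit, stricter thresholds, a replicate block, medians in place of means for the species difference, and each library left out in turn. The clock list was also tested without efflux carriers, which its wording had caught, a choice made after seeing the data. All per-library count columns were used.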

Results

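Transcript levels were measured by RNA sequencing in the first true leaf of common bean (*Phaseolus vulgaris*) and lima bean (*Phaseolus lunatus*), in detached leaves that were left clean or infested with the spider mite *Tetranychus urticae* for 24 h. Each of the 4 groups held 3 libraries. Total counts ran from 17264823 to 19343807 per library in *P. vulgaris* and from 13317991 to 17255676 in *P. lunatus*. The series asks how the responses of the species to mite infestation differ, and its title sets cyanogenic against non-cyanogenic legumes. Log2 fold changes are infested minus control ± a standard error computed back from the fold change and its quasi-likelihood F statistic (n = 3 against 3). CPM values are means ± SD (n = 3). The share of counts in the 20 most counted genes was 7.19% to 8.20% in *P. vulgaris*, 11.1% to 11.96% in *P. lunatus* controls and 14.0% to 14.9% in infested *P. lunatus*.

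The first comparison, infested against control leaves of *P. lunatus*, asks which transcripts changed in lima bean. Called genes of jasmonate synthesis and signalling, of terpenoid volatile synthesis, protease inhibitors and WRKY factors were mostly higher, and those of photosynthesis and chlorophyll synthesis mostly lower. These lists passed camera with its preset correlation, and each had an adjusted p of 0.2 to 0.518 with an estimated correlation. The strongest single call among the jasmonate enzymes was a 13S-lipoxygenase, which makes the first intermediate of jasmonate from linolenic acid (Pl06G0000306200.v1, chromosome 6, 33964765 to 33969330), from 15.1 ± 1.16 to 416 ± 81.1 CPM. A geranylgeranyl pyrophosphate synthase, which makes a precursor of terpenoids (Pl08G0000413100.v1, chromosome 8, 55554620 to 55556296), rose from 17.9 ± 2.15 to 439 ± 16.5 CPM. The light-harvesting protein CP26 (Pl07G0000132400.v1, chromosome 7, 13179252 to 13181803) fell from 954 ± 3.86 to 363 ± 110 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3170 of 18523 tested genes changed, 1788 higher and 1382 lower, and 1264 of them changed at least 2-fold, 821 up and 443 down. The balance of directions depended on the scaling, with 1578 higher and 1680 lower under upper-quartile factors and 1614 and 1612 under library totals. At an unadjusted p below 0.05 there were 6015 genes, and 37.9% of tested genes had ranges that did not overlap, where chance gives 10%. The count fell to 1485 without infested library 2 and to 1317 without infested library 3, and it was 2066 without control library 3.

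Jasmonate synthesis was among the groups with the largest shift in *P. lunatus*. Of 40 measured members of the list, 26 rose and 2 fell, with a median log2 fold change of 1.23 (27 and 5 adjusted over the list alone). The list passed camera (adjusted p = 8.61e-11; adjusted p = 0.321 with an estimated correlation). Beside the lipoxygenase Pl06G0000306200.v1 (log2 fold change 4.78 ± 0.18, adjusted p = 1.98e-05), 13S-lipoxygenases Pl02G0000359900.v1 and Pl10G0000321400.v1 rose by 3.10 ± 0.22 and 2.57 ± 0.16. The enzymes of the next steps, chosen after their values were seen, rose too. Allene oxide synthase 3 (Pl03G0000013200.v1) rose by 1.66 ± 0.15, allene oxide cyclase (Pl04G0000080700.v1) by 3.89 ± 0.28 and 12-oxophytodienoate reductase 3 (Pl03G0000203100.v1) by 1.68 ± 0.12. Putative 12-oxophytodienoate reductase 11 (Pl09G0000018700.v1) was the largest fall of any gene named by the rule, at −3.24 ± 0.73 (adjusted p = 0.0198), and its call ended without infested library 2 (adjusted p = 0.0801) or 3 (adjusted p = 0.089).

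Of 42 members of the jasmonate signalling and turnover list, 20 rose and 2 fell, with a median of 0.60 (20 and 3 adjusted over the list alone). The list passed camera (adjusted p = 1.23e-07; adjusted p = 0.446 with an estimated correlation), and the median was 0.60 also with its 1 member without control counts set at its bound. TIFY 10B (Pl10G0000320100.v1) and TIFY 10A (Pl09G0000318400.v1), members of the family of jasmonate repressors that jasmonate itself induces, rose by 3.02 ± 0.15 and 2.91 ± 0.16, the former from 49.4 ± 1.53 to 401 ± 68.4 CPM. A jasmonate-induced oxygenase 2, of a group of enzymes that inactivate jasmonic acid (Pl08G0000109200.v1, chromosome 8, 9856325 to 9860488), rose from 0.612 ± 0.534 to 145 ± 49.0 CPM (adjusted p = 0.00011), and a further copy (Pl01G0000397900.v1) rose by 2.60 ± 0.13.

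Of 30 members of the terpenoid volatile list, 20 rose and 3 fell, and the median of 2.49 was the highest of all lists in *P. lunatus* (21 and 3 adjusted over the list alone). The list passed camera (adjusted p = 6.52e-09; adjusted p = 0.2 with an estimated correlation). Alpha-farnesene synthase (Pl11G0000015600.v1) rose from 36.2 ± 10.9 to 955 ± 117 CPM (4.72 ± 0.24), and a probable terpene synthase 11 (Pl05G0000218800.v1) from 6.02 ± 2.31 to 263 ± 47.6 CPM. A 1-deoxy-D-xylulose-5-phosphate synthase 2 (Pl03G0000380500.v1), at the entry of the plastid route to terpenoids and chosen after its values were seen, rose by 5.55 ± 0.54.

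Protease inhibitors, which block digestive enzymes of herbivores, had 4 of 13 members higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.37 and camera adjusted p = 0.00441 (adjusted p = 0.518 with an estimated correlation). A Kunitz-type trypsin inhibitor-like 2 protein (Pl04G0000322700.v1) rose from 288 ± 9.75 to 1727 ± 312 CPM. Kunitz-type inhibitor-like 1 (Pl04G0000330400.v1) rose by 2.63 ± 0.18 and trypsin inhibitor A (Pl08G0000170800.v1) by 2.71 ± 0.28. WRKY transcription factors, regulators of stress and defence genes, had 15 of 57 members higher and 1 lower (20 and 2 adjusted over the list alone; camera adjusted p = 0.00044; adjusted p = 0.518 with an estimated correlation). WRKY 69 (Pl05G0000193900.v1), WRKY 40 (Pl05G0000295500.v1) and WRKY 6 (Pl05G0000225300.v1) rose by 1.70 ± 0.15, 2.13 ± 0.19 and 2.24 ± 0.21. Calcium signalling genes had 28 of 105 members higher and 3 lower (33 and 7 adjusted over the list alone), with a median of 0.16 and camera adjusted p = 0.00146 (adjusted p = 0.446 with an estimated correlation). The calcium-binding proteins KIC (Pl10G0000306600.v1) and CML26 (Pl02G0000465200.v1) rose by 1.85 ± 0.12 and 2.14 ± 0.15.

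Photosynthesis genes formed the largest falling group in *P. lunatus*. Of 87 measured members, 53 fell and 1 rose, with a median of −0.98 (62 and 1 adjusted over the list alone; camera adjusted p = 1.16e-16; adjusted p = 0.446 with an estimated correlation). The antenna protein CP29.3 (Pl01G0000395800.v1) fell from 509 ± 147 to 115 ± 44.6 CPM (−2.15 ± 0.31, adjusted p = 0.00332), and photosystem I chlorophyll a/b-binding protein 6 (Pl09G0000318600.v1) by −1.91 ± 0.26. Of 25 genes of chlorophyll synthesis, 11 fell and 0 rose, with a median of −0.55 (12 and 0 adjusted over the list alone; camera adjusted p = 0.000125; adjusted p = 0.518 with an estimated correlation). The protochlorophyllide-dependent translocon component 52 (Pl02G0000366800.v1) fell by 0.88 on the log2 scale. The ChlH subunit of magnesium chelatase (Pl01G0000272800.v1) fell from 1292 ± 159 to 577 ± 203 CPM, a call that ended without infested library 2 (adjusted p = 0.0646) or 3 (adjusted p = 0.0653). The circadian clock list, a check of collection time, moved beside these groups with 8 of 41 members lower and 1 higher (10 and 1 adjusted over the list alone), a median of −0.32 and camera adjusted p = 0.00228 (adjusted p = 0.446 with an estimated correlation). The pseudo-response regulator APRR5 (Pl10G0000311500.v1), an evening-phase repressor, fell by 0.86 on the log2 scale, and REVEILLE 5 (Pl08G0000065400.v1), of the morning-phase REVEILLE family, fell by 0.80. Auxin response genes had 9 of 80 members lower and 5 higher (9 and 6 adjusted over the list alone), with camera adjusted p = 0.0379 (adjusted p = 0.446 with an estimated correlation). Auxin-induced protein 22B (Pl07G0000128400.v1) fell by 0.84, and the auxin list's call ended without any of 4 libraries, at an adjusted p of up to 0.187 without control library 3 or infested library 2.

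**Figure D1:**
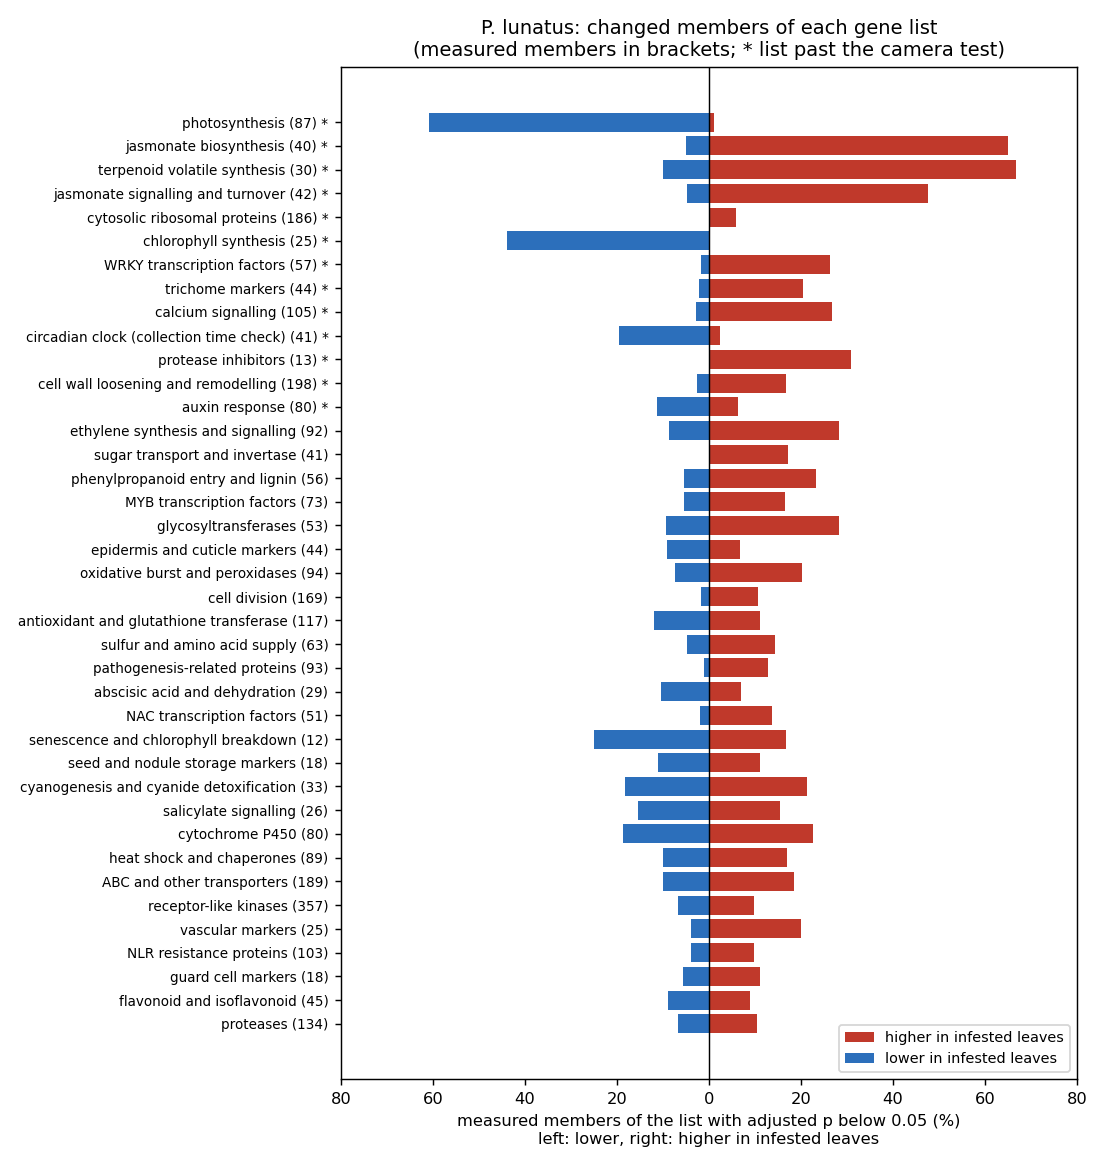
Share of measured members of each gene list (percent, horizontal axis) that were called higher (red, right) or lower (blue, left) in infested *P. lunatus* leaves, with the number measured in brackets and a star at the lists past camera. Photosynthesis stands out to the left with 53 of 87 members lower, and terpenoid volatile synthesis to the right with 20 of 30 members higher.

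Further lists passed camera as well. Cytosolic ribosomal proteins had 11 of 186 members higher and 0 lower, with a median of 0.19 and camera adjusted p = 2.41e-05 (adjusted p = 0.592 with an estimated correlation), but 0 members in either direction adjusted over the list alone. Without control library 3 that list had an adjusted p of 0.0692. Cell wall genes had 33 of 198 members higher and 5 lower (37 and 6 adjusted over the list alone; camera adjusted p = 0.01; adjusted p = 0.446 with an estimated correlation). Pectin acetylesterase 8 (Pl02G0000063200.v1) rose by 2.14 ± 0.16, and a non-catalytic polygalacturonase subunit (Pl03G0000058600.v1) rose from 408 ± 35.7 to 1425 ± 302 CPM. The trichome list had 9 of 44 members higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.00121; adjusted p = 0.446 with an estimated correlation). Most of its members are trichome birefringence-like proteins, which acetylate cell wall polymers in many tissues, and numbers 39 (Pl05G0000199200.v1) and 25 (Pl10G0000302200.v1) rose by 1.72 ± 0.20 and 1.51 ± 0.19. GLABRA 2 (Pl10G0000340900.v1), a homeodomain factor of epidermal cell fate, rose from 12.6 ± 1.11 to 69.9 ± 3.74 CPM.

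The list for the title's subject, cyanogenesis and cyanide detoxification, gave a mixed picture in *P. lunatus*. Its wording also matches rhodaneses, nitrilases, alternative oxidases and some P450s and glycosyltransferases, whose names do not establish a role in cyanogenesis. Its counts are thus not of cyanogenesis genes alone. Of its 33 measured genes, 7 rose and 6 fell (8 and 11 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.486; adjusted p = 0.537 with an estimated correlation). Its median was −0.21 and its mean 0.31. The P450 named CYP736A12 (Pl04G0000355900.v1) rose from 3.78 ± 1.28 to 28.8 ± 11.4 CPM. The rhodanese-like protein 15 (Pl02G0000075000.v1) fell by 1.13 on the log2 scale. An isoleucine N-monooxygenase (Pl06G0000006800.v1), of the enzyme group that starts cyanogenic glucoside synthesis, rose from 0.355 ± 0.291 to 4.42 ± 2.39 CPM. A cyanoalanine synthase (Pl08G0000067700.v1), which binds cyanide to cysteine, rose from 307 ± 37.8 to 589 ± 217 CPM (adjusted p = 0.0409). A fragment annotated as cyanogenic beta-glucosidase (Pl05G0000264500.v1) had 1.57 ± 0.617 and 5.71 ± 3.40 CPM (adjusted p = 0.0496). These 3 genes were chosen after their values were seen. The calls of the synthase and the fragment each ended with any of 5 libraries left out, at an adjusted p of up to 0.140 and 0.164 without infested library 3, and the ranges of the fragment overlap. The fragment's call also ended with median-ratio scaling (adjusted p = 0.0502), library totals (adjusted p = 0.0516), upper-quartile factors (adjusted p = 0.0531) and the robust fit (adjusted p = 0.0531).

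Salicylate signalling had 4 of 26 members higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.562), with SAR DEFICIENT 1 (Pl02G0000454300.v1) higher by 1.55 ± 0.28 and TGA1 (Pl01G0000403700.v1) lower, at −0.74 ± 0.10. The ethylene list had 26 of 92 members higher and 8 lower (28 and 12 adjusted over the list alone) without passing camera (adjusted p = 0.0906). Called members include homologs of 1-aminocyclopropane-1-carboxylate oxidase, whose names do not establish that they make ethylene. A 1-aminocyclopropane-1-carboxylate synthase (Pl02G0000428600.v1), the enzyme that makes the ethylene precursor, rose from 6.72 ± 5.63 to 156 ± 61.6 CPM. Phenylpropanoid genes had 13 of 56 higher and 3 lower (14 and 4 adjusted over the list alone; camera adjusted p = 0.149), and flavonoid genes 4 of 45 higher and 4 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.979). Among amino acid supply genes, 9 of 63 were higher and 3 lower (9 and 3 adjusted over the list alone; camera adjusted p = 0.286). Tryptophan synthase beta chain 2 (Pl02G0000006700.v1) rose from 21.5 ± 8.25 to 295 ± 39.8 CPM, and anthranilate phosphoribosyltransferase (Pl09G0000252400.v1) by 2.97 ± 0.16.

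**Figure D2:**
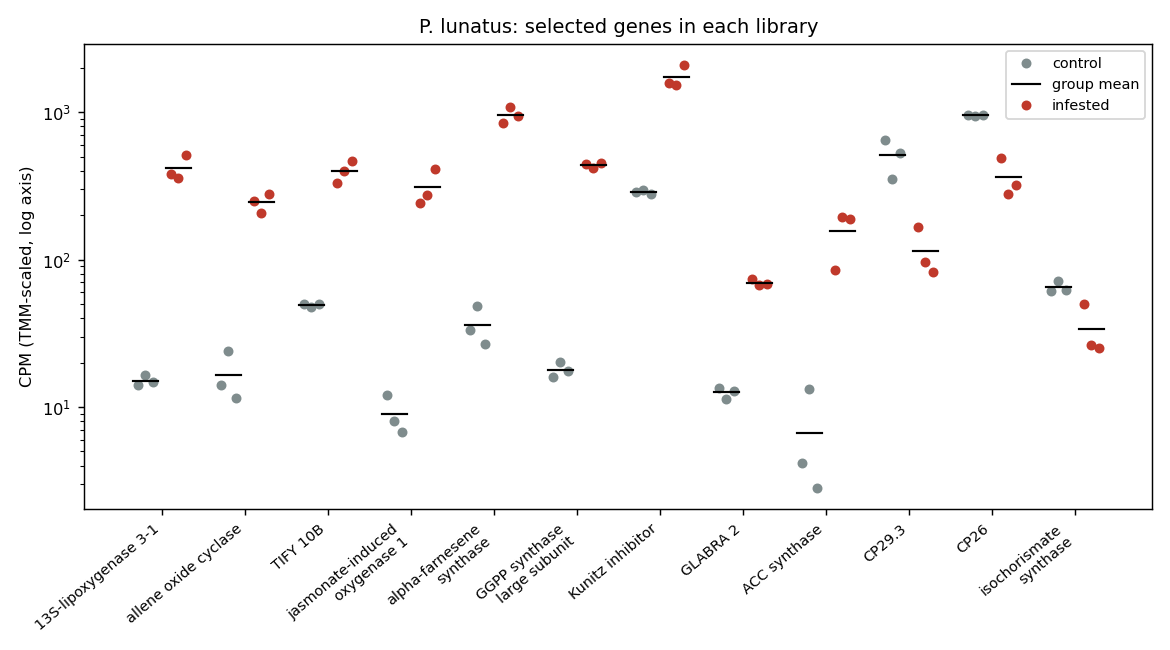
CPM (log axis) of 12 genes, selected for plotting after their values were seen, in each of the 3 control (grey) and 3 infested (red) *P. lunatus* libraries, with the group mean as a line. The 13S-lipoxygenase moves from a mean of 15.1 to 416 CPM, while CP26 moves from 954 to 363 CPM.

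Among the 10 largest rises in *P. lunatus* that the rule names, an alpha-dioxygenase 1, which oxidises fatty acids (Pl04G0000018900.v1, chromosome 4, 1563561 to 1568619), rose from 1.54 ± 1.05 to 193 ± 95.7 CPM and peroxidase 12 (Pl04G0000129800.v1) from 0.380 ± 0.179 to 72.1 ± 42.7 CPM. A CEN-like protein 2 (Pl01G0000340500.v1) and a phenolic glucoside malonyltransferase 2 (Pl08G0000034200.v1) had 0 control counts and were at least 68.6-fold and at least 63.5-fold higher. Others were the acyltransferase RAM2 (Pl07G0000353400.v1, 5.80 ± 0.50) and a glutelin-like storage protein (Pl02G0000381500.v1, 5.60 ± 0.59). The falls included a GATA factor 22 (Pl09G0000054900.v1, −2.33 ± 0.32), of a family that includes regulators of greening, and cysteine-rich receptor-like kinase 29 (Pl07G0000053700.v1, −2.18 ± 0.23).

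The second comparison, infested against control leaves of *P. vulgaris*, asks the same of common bean. Few genes passed, and 181 of 189 were higher. A gene of the hemopexin family (PHAVU_007G276200g, chromosome 7, 51369151 to 51370011) rose from 3.95 ± 1.75 to 273 ± 71.2 CPM. Of 21 genes of the lipoxygenase family, 10 rose and 1 fell, in a set that passed camera but had an adjusted p = 0.809 with an estimated correlation. Among the rises, PHAVU_011G056500g went from 32.6 ± 11.4 to 298 ± 23.1 CPM. Kunitz trypsin inhibitor 2 (PHAVU_004G138500g, chromosome 4, 41714841 to 41715811), which blocks digestive proteases, rose from 7.28 ± 1.61 to 56.5 ± 8.91 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 189 of 19360 tested genes changed, 181 higher and 8 lower, and 132 changed at least 2-fold, 131 up and 1 down. At an unadjusted p below 0.05 there were 2042 genes, and DESeq2 called 455, 390 higher and 65 lower. Ranges did not overlap in 17% of tested genes, where chance gives 10%. The count was 92 without infested library 1, 100 without infested library 2, 100 without control library 2 and 122 without control library 3, and without infested library 2 all 100 called genes were higher.

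Of the 189 called *P. vulgaris* genes, 3 carry a product name. Beside the Kunitz inhibitor (2.96 ± 0.18, adjusted p = 6.63e-05), PGIP1, a polygalacturonase-inhibiting protein (PHAVU_009G1804000g, chromosome 9, 26521123 to 26521909), rose from 2.73 ± 0.0984 to 14.99 ± 0.231 CPM (2.45 ± 0.17, adjusted p = 0.000162). A hevein-like preproprotein, of a chitin-binding group (PHAVU_006G102200g, chromosome 6, 21898967 to 21901131), rose from 140 ± 34.5 to 321 ± 13.2 CPM (1.19 ± 0.15, adjusted p = 0.00682).

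A domain family was given for 102 called *P. vulgaris* genes. The PALP family includes tryptophan synthase beta chains and also the cyanoalanine synthase of *P. lunatus* named above. Its *P. vulgaris* gene PHAVU_002G048100g rose from 4.99 ± 1.71 to 134 ± 24.4 CPM (4.75 ± 0.23, adjusted p = 3.88e-05). This gene has no product name, so which of these enzymes it encodes, if either, is not known. A 2OG-FeII_Oxy oxygenase (PHAVU_010G000300g) rose by 4.51 ± 0.24, an ADH_N dehydrogenase (PHAVU_008G207900g) by 4.01 ± 0.28, a p450 (PHAVU_011G092100g) by 6.09 ± 0.76 and a WRKY gene (PHAVU_010G057900g) by 4.43 ± 0.48. A gene of the An_peroxidase family, to which the alpha-dioxygenase of *P. lunatus* also belongs (PHAVU_004G018900g), rose from 1.54 ± 1.21 to 51.5 ± 22.7 CPM, and a robust fit ended its call (adjusted p = 0.0546). Another 2OG-FeII_Oxy gene (PHAVU_002G232800g) had 0 control counts and was at least 67.4-fold higher. The falls were small. The SBP gene PHAVU_008G157100g, of a family of plant transcription factors, fell from 16.7 ± 3.11 to 7.37 ± 0.318 CPM (−1.18 ± 0.17, adjusted p = 0.0137), and its call ended without infested library 1 (adjusted p = 0.0675), infested library 2 (adjusted p = 0.0614) or control library 2 (adjusted p = 0.0616). The zf-CCCH gene PHAVU_002G306100g fell by 0.49 on the log2 scale, and its call ended with any library left out, at an adjusted p of up to 0.122.

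**Figure D3:**
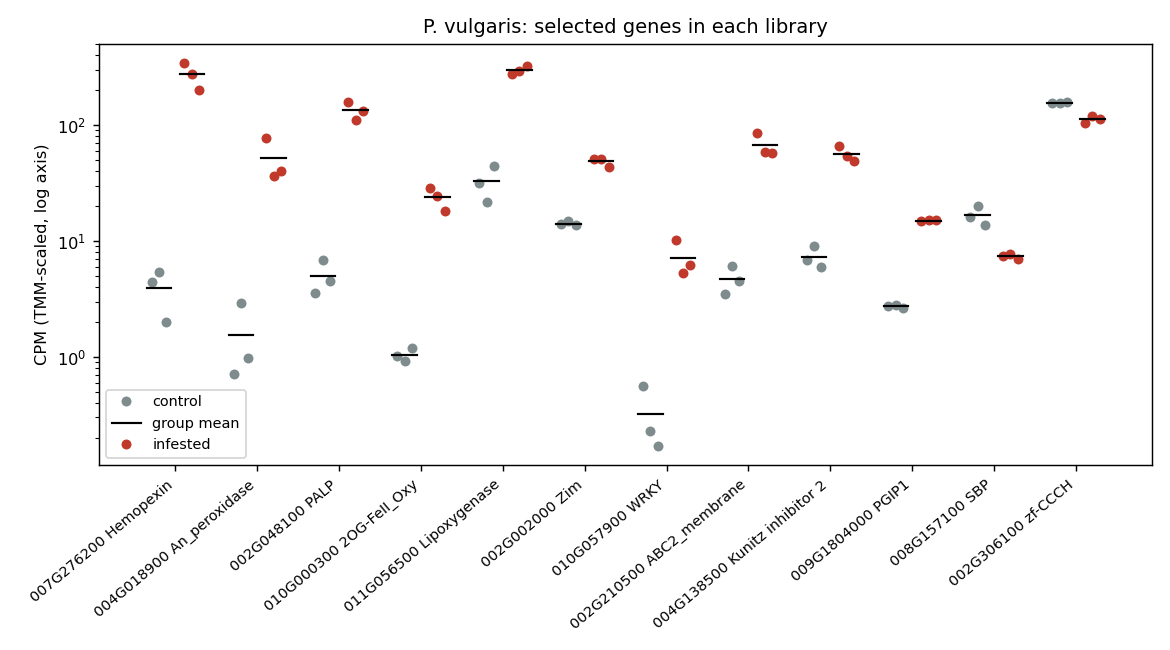
CPM (log axis) of 12 genes, selected for plotting after their values were seen and named by ID and domain family or product, in each of the 3 control (grey) and 3 infested (red) *P. vulgaris* libraries, with the group mean as a line. The hemopexin gene moves from a mean of 3.95 to 273 CPM, and the SBP gene from 16.7 to 7.37 CPM.

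Product names were too few in *P. vulgaris* for most of the 39 lists. Camera tested 11 lists and 0 passed, 2 of them had an unadjusted p below 0.05, and fry and the estimated correlation passed 0. Those 2 were calcium signalling, with a median of 0.37 over 7 members, and photosynthesis, with a median of −0.15 over 8 members (adjusted p = 0.116 each), and 0 members of either list changed in either direction (0 adjusted over the list alone). Single members of other lists included 1 jasmonate synthesis gene (PHAVU_001G012300g) with a log2 fold change of 1.27 that was not called over all genes (1 adjusted over the list alone), and 4 WRKY genes of which 0 were called (1 adjusted over the list alone).

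Among 294 domain family sets, chosen after the annotation had been seen, 12 passed camera in *P. vulgaris*, 10 up and 2 down, and 0 held with an estimated correlation. The Lipoxygenase family had 10 of 21 genes higher and 1 lower (13 and 1 adjusted over the list alone), with a median of 0.86 (camera adjusted p = 1.12e-08; adjusted p = 0.809 with an estimated correlation). Its member PHAVU_005G156900g, already abundant, rose from 4202 ± 359 to 7407 ± 368 CPM, a call that ended without infested library 2 or any control library, at an adjusted p of up to 0.0878. The Zim family, the domain of jasmonate repressors, had 3 of 12 genes higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 9.81e-07; adjusted p = 0.809 with an estimated correlation). Zim genes PHAVU_002G002000g, PHAVU_010G127400g and PHAVU_009G225300g rose by 1.78 ± 0.10, 1.15 ± 0.09 and 1.09 ± 0.12. WRKY genes had 4 of 63 higher and 0 lower (9 and 0 adjusted over the list alone; camera adjusted p = 2.61e-05; adjusted p = 0.922 with an estimated correlation). The other rises were Peptidase_M20 (1 of 14 genes higher, camera adjusted p = 0.000636), Histone (0 of 32, adjusted p = 0.000636), Oxidored_FMN (2 of 8, adjusted p = 0.00216), Chal_sti_synt_N (1 of 8, adjusted p = 0.00408), 2OG-FeII_Oxy (7 of 56, adjusted p = 0.00408), PALP (1 of 18, adjusted p = 0.0207) and MCM (0 of 8, adjusted p = 0.0483). Auxin_resp (0 of 25 lower, adjusted p = 0.00282) and Myosin_head (0 of 14, adjusted p = 0.0483) passed downward. All 9 of these had an adjusted p of 0.922 with an estimated correlation. Leaving out 1 library ended the call of 2OG-FeII_Oxy (infested 1), and of Auxin_resp, Chal_sti_synt_N, MCM, Myosin_head and PALP for at least 2 choices of library, at an adjusted p of up to 0.382 for MCM without infested library 3.

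The same 294 families gave 14 calls in *P. lunatus*, 11 up and 3 down, and 0 held with an estimated correlation (adjusted p = 1 for each). Zim had 9 of 12 genes higher (median 1.22), Lipoxygenase 13 of 18 higher and 1 lower (median 1.69), Peptidase_M20 4 of 11 higher, Lipase_3 10 of 31 higher, GHMP_kinases 5 of 10 higher, Proteasome 6 of 22 higher and Histone 7 of 25 higher. Auxin_resp had 5 of 26 genes lower and 1 higher, Rhodanese 2 of 12 lower and Exo_endo_phos 4 of 24 lower. WRKY (15 of 57 higher), Adap_comp_sub (4 of 11), Glyco_transf_8 (5 of 35) and Ras (9 of 61) completed the rises. Families past the test upward in both species were Histone, Lipoxygenase, Peptidase_M20, WRKY and Zim, 5 families where independent lists would share 0.374 (Fisher's exact test, p = 6.03e-06). Auxin_resp was past it downward in both, where 0.0204 would be shared (Fisher's exact test, p = 0.0203), a result that rests on 1 family. Both Fisher tests treat families as independent draws. Genes of different families can move together, so both p-values are likely too small. Leaving out infested *P. lunatus* library 3 ended the calls of Histone (adjusted p = 0.0784), Auxin_resp (adjusted p = 0.0555), Rhodanese (adjusted p = 0.0614), Exo_endo_phos (adjusted p = 0.117) and Ras (adjusted p = 0.18). The Auxin_resp call also ended without control library 3 (adjusted p = 0.0761) and the Rhodanese call without control library 1 (adjusted p = 0.0587). Ras lost its call without any of 3 libraries and Exo_endo_phos without any of 4, at an adjusted p of up to 0.18 and 0.154, and Exo_endo_phos also with median-ratio scaling (adjusted p = 0.0511).

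The third comparison asks whether the infestation effect itself differed between the species. Members of a family or list were not matched between the species, so a difference can also come from which genes were measured. Over 294 families, the effect in *P. lunatus* correlated with that in *P. vulgaris* (Pearson's r = 0.686, Spearman's rho = 0.512, permutation p = 1e-05 each, the smallest that 100000 permutations can give; 2 relations were computed). Families are not independent replicates, and r was 0.632 without Chal_sti_synt_N and Lipoxygenase, the families farthest from the median. The sign was shared by 201 families (68.4%). The Zim family rose by 0.81 in *P. vulgaris* and 1.67 in *P. lunatus*, a difference of 0.854 (95% CI 0.551 to 1.16, limma adjusted p = 0.0171). Peptidase_M20, which holds hydrolases of amino acid conjugates of auxin, had effects of 0.36 and 0.98, a difference of 0.627 (95% CI 0.369 to 0.886, adjusted p = 0.0207). The Fer2 family of ferredoxins had effects of −0.05 and −0.62, a difference of −0.569 (95% CI −0.847 to −0.291, adjusted p = 0.0307). This call, the only negative one, ended without any of 10 of the 12 libraries (adjusted p of up to 0.0889) and with medians in place of means (−0.412, adjusted p = 0.376). The interaction passed for 9 of 294 families, 8 with a positive and 1 with a negative difference, and 50 had an unadjusted p below 0.05. The count was 0 without infested *P. lunatus* library 2 and 0 without infested library 3, and 19 without infested library 1. It was 3 without *P. vulgaris* control library 1 or *P. lunatus* control library 2, 4 without *P. lunatus* control library 3, and 5 without *P. vulgaris* control library 3 or infested library 2. The size of the differences moved less than the calls: Zim differed by 0.868 without infested library 2 (adjusted p = 0.0511) and by 0.784 without infested library 3 (adjusted p = 0.0501), and the 9 families then had an adjusted p of 0.0501 to 0.127. The Lipoxygenase family had effects of 1.13 and 1.48, with a difference of 0.354 (95% CI 0.161 to 0.547) that did not pass (adjusted p = 0.0545).

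**Figure D4:**
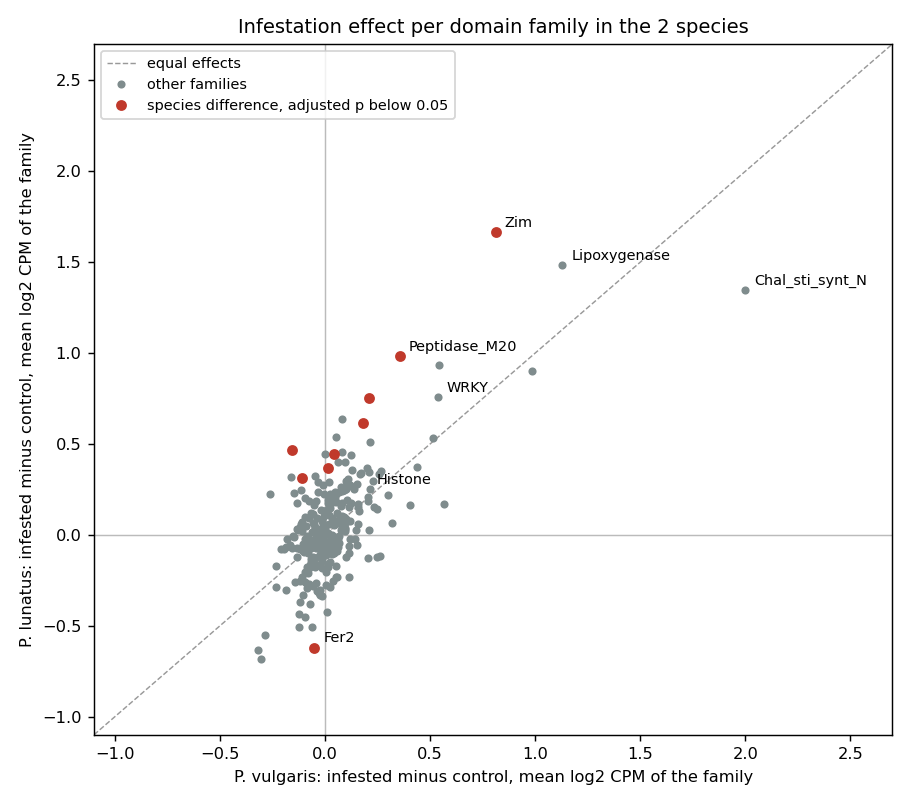
Infestation effect (infested minus control, mean log2 CPM of the family) of 294 domain families in *P. vulgaris* (horizontal) and *P. lunatus* (vertical), with the 9 families past the species difference test in red and equal effects as a dashed line. Zim lies above the line at 0.81 and 1.67, and Fer2 below it at −0.05 and −0.62.

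Among 11 product lists measured in both species, 0 passed the limma test of the difference, and 2 had an unadjusted p below 0.05. Photosynthesis had effects of −0.22 in *P. vulgaris* (8 genes) and −0.90 in *P. lunatus*, with a difference of −0.678 (95% CI −1.21 to −0.142, adjusted p = 0.117). Chlorophyll synthesis had effects of −0.02 and −0.56, with a difference of −0.542 (95% CI −0.986 to −0.0979, adjusted p = 0.117). The cyanogenesis list could not be compared, since 2 members with a product name were measured in *P. vulgaris*, with 0 called in either direction (0 adjusted over the list alone).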

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

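The domain family sets, and with them every test in this part, were chosen only after the annotation had been seen. In 9 of 294 families the infestation effect differed between the species by the interaction test of limma (adjusted p below 0.05), each value being the effect in *P. lunatus* minus that in *P. vulgaris* on the log2 scale. The jasmonate repressor family Zim differed by 0.854 (adjusted p = 0.0171), Peptidase_M20 by 0.627 (adjusted p = 0.0207) and the phospholipase family PI-PLC-X by 0.622 (adjusted p = 0.0183). GHMP_kinases differed by 0.546 (adjusted p = 0.0265), Lipase_3 by 0.436 (adjusted p = 0.0307) and Glyco_transf_8 by 0.422 (adjusted p = 0.0419). Adap_comp_sub differed by 0.399 (adjusted p = 0.0212) and the chloride channel family Voltage_CLC by 0.352 (adjusted p = 0.0276). The ferredoxin family Fer2 differed by −0.569 (adjusted p = 0.0307).

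Of 100 splits of the libraries within the species, 8 gave at least 9 families, the real one included, and the highest of the others gave 56. All 8 keep the real control and infested groups of *P. lunatus*, and with them its infestation effect, and apart from the real split they regroup only *P. vulgaris*. They are thus no test of equal effects in both species, and their number leaves open whether chance is excluded. Of the splits that keep only the real *P. vulgaris* groups or neither species' groups, 0 gave as many. With each of the 12 libraries left out in turn, the calls of Fer2 and Glyco_transf_8 ended 10 times each, those of GHMP_kinases and Lipase_3 9 times each, and that of Voltage_CLC 8 times. With infested *P. lunatus* library 2 or 3 left out, 0 of the 9 families passed, at an adjusted p of 0.0501 to 0.127, with differences of similar size. Zim differed by 0.868 and 0.784 and PI-PLC-X by 0.602 and 0.623 without library 2 and 3. With medians in place of means, 2 of the 9 kept their call and PI-PLC-X changed sign (−0.0710). No explanation of the differences was weighed.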

How the results depend on the processing

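Tests on domain families and the clock list without efflux carriers were chosen after seeing the data. Under the other scalings, filters and fits not named here, each count stayed within 1.5 times its value, and DESeq2 called 3724 *P. lunatus* genes against 3170. For *P. vulgaris* genes (189), DESeq2 gave 455 (390 higher, 65 lower), an adjusted p below 0.01 gave 77, and leaving out 1 library gave 92 to 172. For *P. lunatus* genes (3170), a 2-fold minimum gave 1264, an adjusted p below 0.01 gave 1126, and leaving out 1 library gave 1317 to 3204. An estimated correlation left 0 of 13 *P. lunatus* lists, 0 of 14 *P. lunatus* families and 0 of 12 *P. vulgaris* families. Fry, which compares a list with no other genes, passed 19 lists in *P. lunatus*, 11 of them among the 13. It passed 6 families in *P. vulgaris*, 3 of them among the 12, and 44 in *P. lunatus*, 9 of them among the 14. Leaving out 1 library gave 0 to 2 lists and 8 to 11 families in *P. vulgaris*, 11 to 15 lists and 9 to 21 families in *P. lunatus*, and 0 to 2 lists and 0 to 19 families for the species difference. With medians in place of means, 1 list and 13 families (2 of the 9) passed the species difference, and PI-PLC-X turned from 0.622 to −0.0710 (adjusted p = 0.93). The cause of these shifts was not tested, except that stricter thresholds leave fewer calls by construction.

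With every library left out in turn, 18 of the 34 single *P. vulgaris* genes followed and 142 of the 178 single *P. lunatus* genes kept their call each time, as did 11 of 13 *P. lunatus* lists, 6 of 12 and 9 of 14 families, and 0 of 9 species differences. Replicate numbers do not pair the libraries by the rule set for them: same-number correlations of deviations were 0.138, 0.0852 and 0.206 in *P. vulgaris* and −0.22, 0.0487 and −0.184 in *P. lunatus*. Each *P. vulgaris* library correlated best with its own number, a hint from the data and not from the design. A replicate block gave 539 *P. vulgaris* genes (405 higher, 134 lower, 189 shared) and 1617 *P. lunatus* genes (1596 shared), and 1 list in *P. vulgaris*. In *P. lunatus* it ended the calls of 27 of the 178 genes, ChlH (adjusted p = 0.0503) and the cyanoalanine synthase (adjusted p = 0.126) among them, of the auxin response list (adjusted p = 0.0576) and of the family Exo_endo_phos (adjusted p = 0.0649). It also ended 3 of the 9 species differences, GHMP_kinases (adjusted p = 0.0957), Glyco_transf_8 (adjusted p = 0.0893) and Voltage_CLC (adjusted p = 0.116). The per-gene species interaction and its alternatives were not run, for want of shared gene IDs. At these depths 2-fold changes were recovered less often than 4-fold ones in simulation, so smaller changes are underrepresented among the calls.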

Other observations

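In this part, the tests of time of day, of sequencing depth, of replicate spread and of mite reads, and the family sets, were chosen only after the result was seen. In *P. lunatus*, glycosyltransferases had 15 of 53 genes higher and 5 lower (16 and 6 adjusted over the list alone; camera adjusted p = 0.217), with UDP-glycosyltransferase 708D1 (Pl04G0000330600.v1) rising from 16.5 ± 3.19 to 235 ± 59.2 CPM. Cytochrome P450 genes went both ways, with 18 of 80 higher and 15 lower (20 and 17 adjusted over the list alone; camera adjusted p = 0.605). P450 72A15 (Pl11G0000003500.v1) rose from 334 ± 17.2 to 1336 ± 201 CPM, while P450 78A3 (Pl10G0000307800.v1) fell by 0.94 on the log2 scale. MYB factors had 12 of 73 higher and 4 lower (12 and 4 adjusted over the list alone; camera adjusted p = 0.149), with MYB73 (Pl01G0000028500.v1) rising by 1.62 ± 0.18 and MYB48 (Pl05G0000252700.v1) falling by 1.63. Among ABC and other transporters, 35 of 189 were higher and 19 lower (38 and 22 adjusted over the list alone; camera adjusted p = 0.65). Peroxidases and other oxidative burst genes had 19 of 94 higher and 7 lower (23 and 10 adjusted over the list alone; camera adjusted p = 0.237). Antioxidant genes had 13 of 117 higher and 14 lower (14 and 19 adjusted over the list alone; camera adjusted p = 0.25). Pathogenesis-related proteins had 12 of 93 higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.286, upward, with a median of −0.01 and a mean of 0.11). The wording of this list also caught regulators and a receptor kinase, the latter as its lower member, so these counts are not of pathogenesis-related proteins alone.

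The remaining *P. lunatus* lists did not pass camera either. Receptor-like kinases had 35 of 357 genes higher and 24 lower (35 and 23 adjusted over the list alone; adjusted p = 0.709), and NLR proteins 10 of 103 higher and 4 lower (9 and 3; adjusted p = 0.8). Heat shock genes had 15 of 89 higher and 9 lower (16 and 11; adjusted p = 0.65), proteases 14 of 134 and 9 (14 and 9; adjusted p = 0.986), and cell division genes 18 of 169 and 3 (13 and 3; adjusted p = 0.25). NAC factors had 7 of 51 higher and 1 lower (7 and 1; adjusted p = 0.286), sugar transport 7 of 41 and 0 (7 and 0; adjusted p = 0.145), abscisic acid genes 2 of 29 and 3 (2 and 3; adjusted p = 0.286), and senescence genes 2 of 12 and 3 (2 and 3; adjusted p = 0.292). The lists kept as checks of tissue gave epidermis markers with 3 of 44 higher and 4 lower (3 and 4; adjusted p = 0.217), vascular markers with 5 of 25 and 1 (5 and 3; adjusted p = 0.8), guard cell markers with 2 of 18 and 1 (2 and 1; adjusted p = 0.97), and seed and nodule markers with 2 of 18 and 2 (3 and 2; adjusted p = 0.362).

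The fall of photosynthesis genes in infested *P. lunatus* was set against 3 technical explanations. A few genes taking most of the counts would lower all other genes alike. With library totals alone, however, the median log2 fold change of all tested genes was −0.043. This argues against such genes as the whole cause. The list median stayed at −0.94 with the 20 most counted genes of each library removed, 38 genes in all, and 75 members left. TMM scaling already sets aside genes of extreme level or change, so the removal by itself decides little. Random lists matched on broad bins of gene length and expression argue against a bias from either. Of 10000 such lists, 0% had a median as low as −0.985, and the lowest reached −0.345. Some members are among the most counted genes, and the bins may not cover bias at that extreme. Time of day of collection cannot be told apart from infestation: morning clock genes averaged −0.275 (95% CI −0.435 to −0.116, 14 genes) and evening ones −0.466 (95% CI −1.01 to 0.0804, 8 genes), which leaves the direction of the evening genes open. A response to infestation, the biological explanation the design gives, may account for the fall and stays a hypothesis, as do different collection times.

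More genes were called in *P. lunatus* (3170) than in *P. vulgaris* (189), which was set against 2 technical explanations. The size of this gap depended on the fit, with 3724 against 455 genes in DESeq2 and 1617 against 539 with a replicate block. Sequencing depth argues the other way, with a ratio of mean totals of 0.806, *P. lunatus* over *P. vulgaris* (0.776 to 0.819 with each library left out). The common coefficient of variation between libraries beyond counting error was 0.179 in *P. vulgaris* and 0.184 in *P. lunatus*. This argues against larger replicate spread in *P. vulgaris* as a cause. Genes with at least a 2-fold change at an average log2 CPM of at least 1 made up 8.58% in *P. lunatus* against 1.85% in *P. vulgaris*. Larger spread in *P. vulgaris* would not by itself give this ratio of 4.63 (3.3 to 6 with each library left out). A difference in the plants' response, in how the mites, reared on *P. vulgaris*, fed on each host, or in the gene models may each contribute, and none of these was tested.

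The Histone family passed camera upward in both species, with medians of 0.17 in *P. vulgaris* (0 of 32 genes called) and 0.38 in *P. lunatus* (7 of 25). The calls were lost with an estimated correlation (adjusted p = 0.922 and adjusted p = 1), and the *P. lunatus* call also without infested library 3 (adjusted p = 0.0784). Gene length or expression level bias is argued against, as far as the broad bins used for matching allow. The median lay above at least 99.9% of matched random lists in both species. Mite reads in the infested libraries were assumed to raise actin, tubulin and elongation factor families as much as histones, which was not tested. The histones exceeded these families with a smaller lower 95% bound of 0.0194 (0.209 in *P. vulgaris*, 95% CI 0.0194 to 0.399, and 0.333 in *P. lunatus*, 95% CI 0.0252 to 0.641). Only under that assumption does this argue against mite reads as the whole cause, and by a narrow margin. Reads shared between near-identical copies stay open: the summed CPM was higher by at least 0.12 on the log2 scale, but the *P. lunatus* ranges overlapped (1417 to 1531 against 1513 to 1776). A response to infestation is a candidate explanation that remains.

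With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, so chance can be neither shown nor ruled out this way. The real split gave 189 genes in *P. vulgaris* and 3170 in *P. lunatus*, where the highest other split gave 0 in each, and it alone (1 of 10) reached these counts. For domain families the real split gave 12 and 14, the highest other 6 in each species, and 1 of 10 splits reached the real count. For product lists the real split gave 13 in *P. lunatus*, against 10 in the highest other (1 of 10 splits), and 0 in *P. vulgaris*, which any split reaches (10 of 10), the highest other giving 3. For the species difference of product lists the real split passed 0 and the highest other 2, and since any split reaches a count of 0 (100 of 100), this says nothing about chance.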
